A study of Solanum lycopersicum with 96 samples.

How the data were processed

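Whole-genome bisulfite sequencing was applied to DNA of tomato (Solanum lycopersicum) seed. Bisulfite converts unmethylated cytosines, so that methylated and unmethylated positions can be told apart in the reads. The labels describe 96 libraries from 8 groups, with 6 replicates per group and 2 libraries per replicate. The series description gives 90 libraries and does not mention BABA in time window 3 for Moneyberg. That group is taken from the labels and its own list, and the comparison of BABA in time windows 2 and 3 rests on them. Each extraction pooled 10 seeds, and the seed of a treatment came from 6 mother plants, per the labels. DNA was extracted with a plant and seed kit from Zymo, libraries were made with a low-input Methyl-Seq kit from Tecan, and paired reads came from a NovaSeq instrument, per the labels' protocols.

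The authors deposited 1 list of genomic regions for each group, so the libraries of a group had been combined before or during the calling of regions. Trim Galore, a read trimmer, is named in the submitters' processing notes without a version. The aligner, the region caller, the genome build, the cytosine context, the methylation thresholds and the way of pooling are not given in the sources used here. Each deposited list has 6 columns and no header: chromosome, start, end, a name beginning with HYPO, a whole number in the score column and a strand that is always plus. The score that the authors deposited for each region grew with its length, with Pearson correlations across regions of 0.899 to 0.938 within the lists. It stood at 17.2 to 17.4 per kb of listed sequence. Of 2997 intervals that are identical in all 8 lists, 83.5% had exactly the same score in every list. The score is therefore read here as the number of cytosine sites in the region, a reading that rests on the values and not on a stated definition. It was used to rank and filter regions within a list. The files give neither methylation levels nor read counts, so the depth behind a region is unknown.

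Groups were taken from the sample labels, and each list was assigned to its group by the description that names it for all 12 libraries of that group. With 1 pooled list per group there is no replicate error, no test between groups was run, and differences between lists are descriptions of these 8 lists. The splits of the lists and the spread over chromosomes given below measure these lists and positions in them, not plants. The regression of methylation levels planned for values per library did not apply. Coordinates are those of the deposited lists, counted from 1. The only gene table at hand belongs to assembly SLM_r2.1, and chromosome ends showed that the lists do not use it, so regions were not assigned to genes. The planned account of regions in genes, exons, introns and upstream sequence and the planned tests of gene lists were therefore not made.

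For each treatment, the list was compared with the control list of the same cultivar. A region was counted as shared when at least 1 base lay in a region of the other list. A region with no shared base was called gained when it stood in the treatment list and lost when it stood in the control list. The Jaccard index is the number of bases in both lists divided by the number in either. It was set beside 100 seeded random placements of the treatment regions within their own chromosomes, without overlap. Shares of regions carry 95% Wilson intervals, which cover counting error over regions and not differences between plants. Chromosome lengths were taken as the last listed base. Chromosomes were divided into bins of 1 Mb and into the first 5 Mb, the last 5 Mb and the part between. The rule set before the data were examined ranked only regions in genes or upstream sequence and named their genes. Without gene assignments it was changed to rank all regions. Named are the 10 gained and the 10 lost regions with the most sites in each comparison, from which examples are given.

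Gained or lost regions of a pair of comparisons were counted as shared when they had a base in common. This count was set beside 100 seeded draws of as many regions from those that could have been gained or lost. For gained regions these were all regions of the other 7 lists with no base in the control list, and for lost regions all regions of the control list. The gained pool holds regions of both compared lists, so a draw can hit a compared list's own gained regions, which raises the drawn counts. Draws were not matched for region size. Within a cultivar the comparisons share a control list, so the bases gained or lost in both were also computed after 100 random reassignments, in which each segment kept its number of lists but not their identity. Overlaps of independent sets were computed as the product of both sizes over the number of bases that could change.

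Alternatives set before the data were examined were a reciprocal overlap of 50%, regions at or above the median number of sites of their list, merging of regions within 100 bases, sharing counted in bases, and a distance of 1000 bases for gained and lost regions. Restricting the lists to the 12 numbered chromosomes removed nothing. Added after seeing the data were a common minimum of 85 sites per region, the highest of the 8 lists' lowest values, leaving out chromosome 9, and leaving out each chromosome in turn as a spread for the ratios of shared gained bases across cultivars. The interval code was tested on simulated data made from chromosome 6 of the control lists: all 187 planted gained and 187 planted lost regions were recovered among 1871 regions in each Moneyberg comparison, and all 175 and 175 among 1759 regions in each Bolstar comparison. Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.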

Results

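The series asked whether treating tomato mother plants with chemical elicitors, compounds that prime plant defence, left a difference in the DNA methylation of their seed. Seed of the cultivars Moneyberg and Bolstar was examined by whole-genome bisulfite sequencing. Moneyberg had a control group and 4 treatments: BABA (beta-aminobutyric acid) in time window 2, BABA in time window 3, Ina in time window 2, and MeJA (methyl jasmonate, an ester of the plant hormone jasmonic acid) in time window 3. Bolstar had a control group and 2 treatments, BABA and Ina, both in time window 2. Each group comprised 12 libraries, 2 for each of 6 replicates, and is represented by 1 pooled list of regions whose names begin with HYPO. The lists do not state a methylation level. The name would stand for low methylation, while most listed sequence lay in chromosome interiors, whose heterochromatin is usually heavily methylated in plants. Which of these holds is not given in the sources used here, so the terms gained and lost refer to listing and not to a direction of methylation. No replicate error exists for any value below, and the read depth behind the regions is unknown.

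The listed regions covered nearly the same amount of sequence in every group. Covered sequence ranged from 448 Mb in Bolstar BABA TW2 to 453 Mb in Bolstar Ina TW2, or 55.5% to 56.1% of the 12 chromosomes. Of all bases listed in any group, 76.4% (385 Mb) were listed in all 8. Numbers of regions differed more, from 24151 in Bolstar BABA TW2 to 32856 in Moneyberg control. The list with the fewest regions had the longest ones, with a median of 12.5 kb against 9.63 kb in Moneyberg control. It also had the highest lower limit, 85 sites per region, against 65 in Moneyberg control.

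The regions lay mainly in the interior of the chromosomes, which in tomato is gene-poor heterochromatin rich in transposable elements, and were sparse towards the gene-rich ends. In the last 5 Mb of the 12 chromosomes 6.3% to 20.6% of bases were listed, and in the first 5 Mb 10.2% to 43.2%, leaving aside chromosome 2. Between these ends the share was 45.3% to 78.4% on the 11 chromosomes other than chromosome 9. Chromosome 2, whose short arm carries the nucleolus organiser, was listed over 75.9% to 78.8% of its first 5 Mb. The interior of chromosome 9 was listed over 23.4% to 27.3% in the 8 groups. Of 13 stretches above 1 Mb without any region in any list, the longest was 4.7 Mb on chromosome 3, from 13380025 to 18082864.

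**Figure D1:**
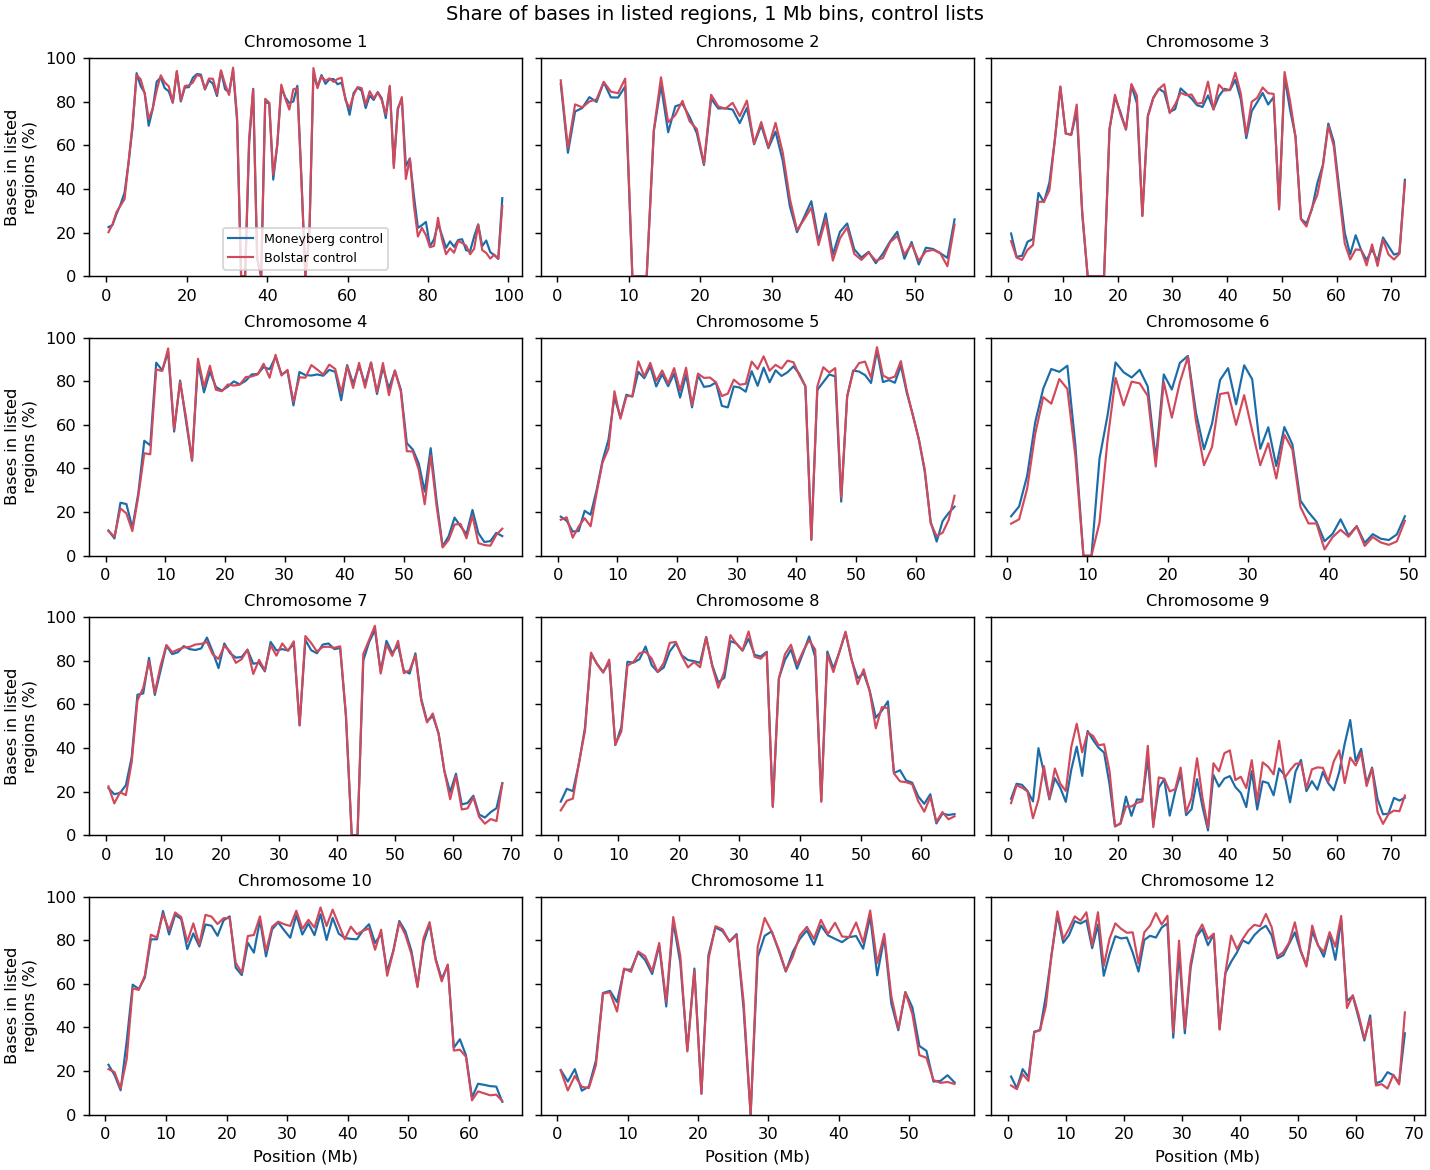
Share of bases in listed regions (%, vertical axis) in bins of 1 Mb along each of the 12 chromosomes (position in Mb, horizontal axis), for the pooled Moneyberg control list and the pooled Bolstar control list. Shares are high in the chromosome interiors and low at most ends, chromosome 2 starts high, chromosome 9 stays low, and the Bolstar line runs below the Moneyberg line over much of chromosome 6.

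In Moneyberg, each treatment was compared with the control to ask how far the elicitor moved the listed regions. The 4 treatment lists were close to the control list, with Jaccard indices of 0.934 for BABA TW2, 0.935 for Ina TW2, 0.936 for BABA TW3 and 0.929 for MeJA TW3. Random placements of the same regions averaged 0.412 to 0.413. The 6 pairs of treatments were as close to one another, at 0.933 to 0.939. Over the whole genome the control's mean index to the other 4 lists was 0.933, and that of MeJA TW3 was also 0.933. By chromosome, every pair with the control lay below every pair of treatments on chromosome 2 (0.937 to 0.942 against 0.949 to 0.955) and on chromosome 6 (0.956 to 0.958 against 0.962 to 0.966). Pairs with the control had a lower mean index than the other pairs on 10 of 12 chromosomes, all but 7 and 9. Pairs with MeJA TW3 also did on 10, and lay below every other pair on chromosome 10. At the common minimum of 85 sites, chosen after seeing the data, these numbers were 7 for the control, 7 for MeJA TW3 and 8 for Ina TW2. Ina TW2 thus came first by this count, in place of the control and MeJA TW3 together. At that minimum every pair with the control lay below every other pair on chromosomes 2 and 11, and pairs with BABA TW2 did so on chromosome 1. Among regions at or above the median site number, chromosome 2 set the control apart and chromosome 8 MeJA TW3. Chromosome 6 set the control apart in neither setting.

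Between 97.1% and 97.3% of the treatment regions shared a base with the control list. For BABA TW2 the share was 97.1% (95% Wilson interval 96.9% to 97.3%), and for Ina TW2 97.3% (97.2% to 97.5%). Gained regions numbered 906 for BABA TW2, 834 for Ina TW2, 864 for MeJA TW3 and 836 for BABA TW3, and lost regions 1516, 1441, 1910 and 1476. Gained regions were small, with median site numbers of 85 to 89, and lost regions smaller, at 70 to 72. Among regions at or above the median site number of their list, 12 to 14 were gained and 6 to 16 lost. Lost regions with fewer sites than the smallest region of the treatment's list numbered 452 for BABA TW2, 231 for Ina TW2, 939 for MeJA TW3 and 447 for BABA TW3. Leaving these out, 1064, 1210, 971 and 1029 lost regions remained, still more than were gained. With the common minimum the direction turned, with 505 gained and 302 lost for BABA TW2, 446 and 386 for Ina TW2, 537 and 347 for MeJA TW3, and 431 and 365 for BABA TW3.

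**Figure D2:**
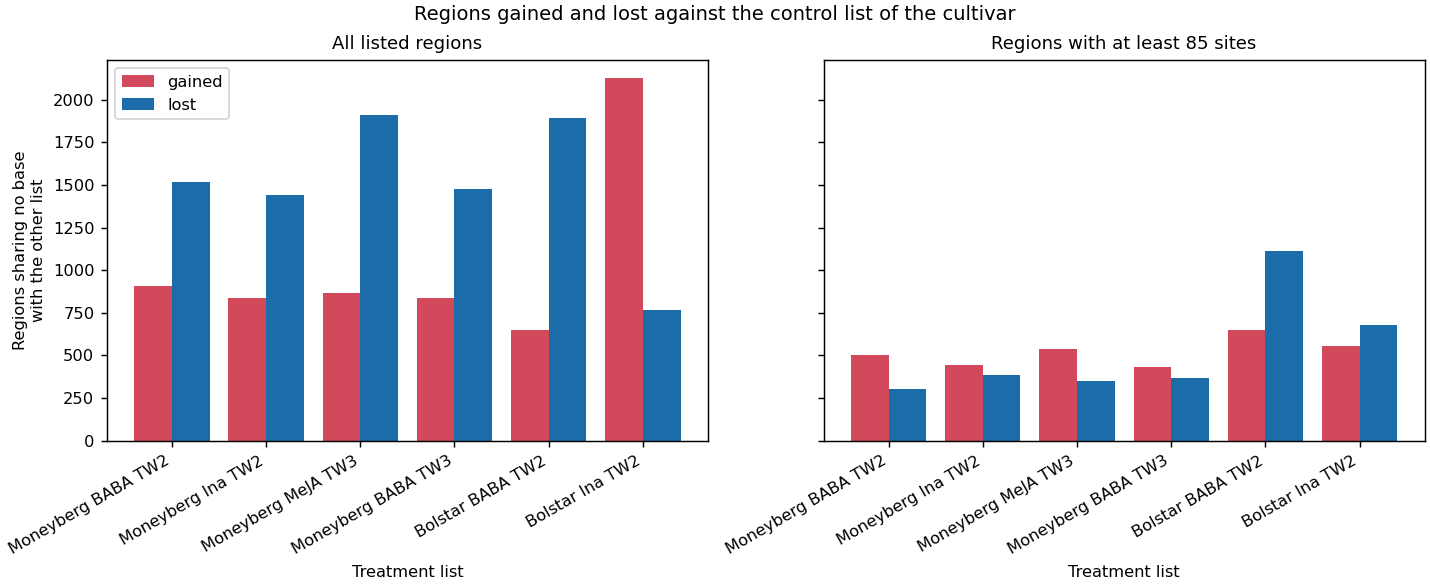
Numbers of regions (vertical axis) gained and lost in each of the 6 treatment lists against the control list of the same cultivar, for all listed regions (left) and for regions with at least 85 sites (right). In the 4 Moneyberg treatments lost regions exceed gained ones on the left (906 gained and 1516 lost for BABA TW2) and fall below them on the right (505 and 302).

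In Bolstar, both treatments were somewhat further from their control than the Moneyberg treatments were from theirs, with Jaccard indices of 0.921 for BABA TW2 and 0.920 for Ina TW2, against 0.413 to 0.415 for random placements. The treatments differed from each other more than either did from the control, with an index of 0.906. BABA TW2 had 646 gained and 1891 lost regions, and Ina TW2 had 2127 gained and 765 lost. Of the BABA TW2 regions 97.3% touched the control list (97.1% to 97.5%), and of the Ina TW2 regions 92.9% (92.6% to 93.2%). The lower limit of the Bolstar Ina TW2 list was 71 sites, against 78 in the control, and 979 of its 2127 gained regions lay below the control's limit, which leaves 1148. At the common minimum of 85 sites Ina TW2 had 556 gained and 679 lost regions, a turn in direction, and BABA TW2 had 646 gained and 1110 lost.

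Differences between treatment and control were concentrated on chromosome 9. It held 27.9% to 30.9% of the bases found in only the treatment or only the control list, over the 6 comparisons, but 2.7% to 3.1% of the bases they shared. The Jaccard index on chromosome 9 was 0.535 to 0.576, against 0.853 to 0.962 on the other 11 chromosomes. The low end of that range came from chromosome 6 in Bolstar, at 0.862 for BABA TW2 and 0.853 for Ina TW2, where the other 10 chromosomes gave Bolstar 0.930 to 0.953 and Moneyberg chromosome 6 gave 0.956 to 0.958. Without chromosome 9, numbers of gained regions were 470 for Moneyberg BABA TW2, 457 for Ina TW2, 450 for MeJA TW3 and 452 for BABA TW3, each more than 1.5 times below the count with it.

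**Figure D3:**
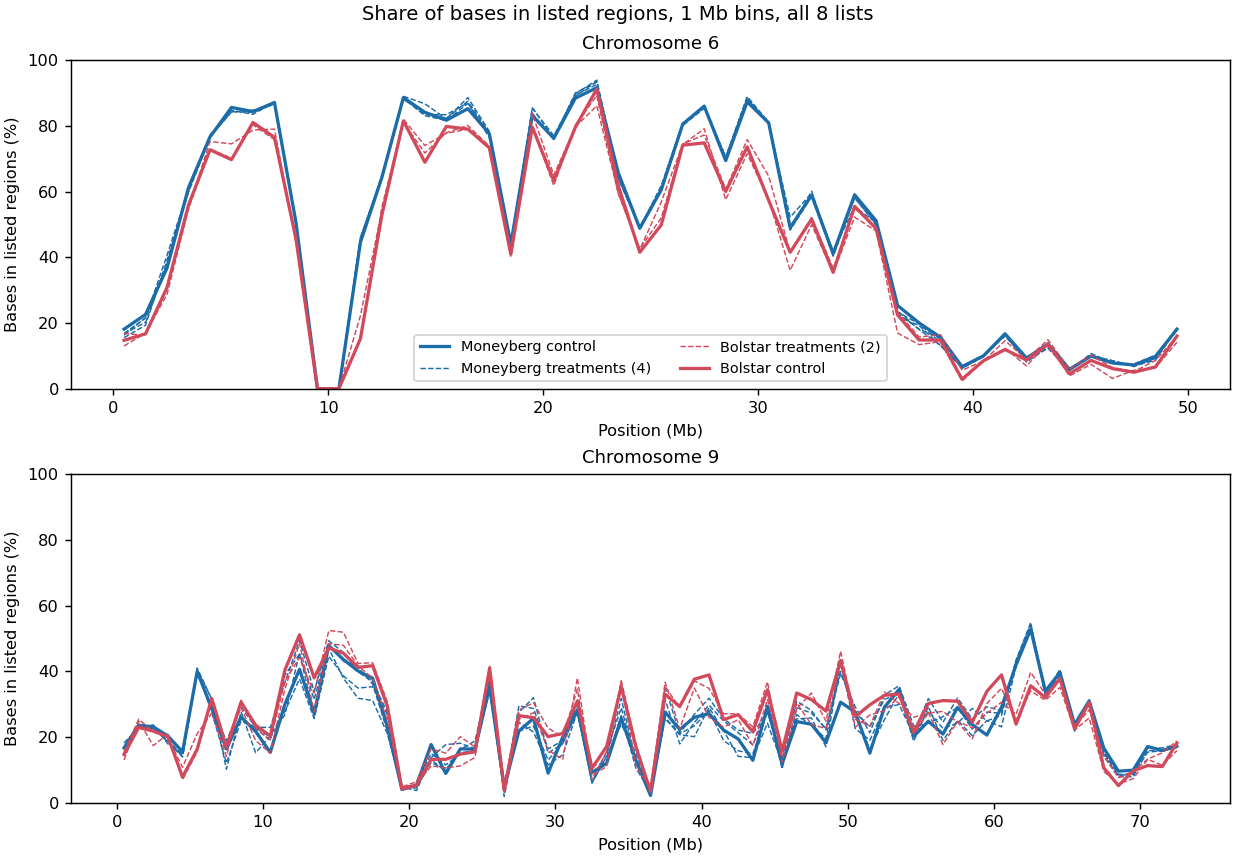
Share of bases in listed regions (%, vertical axis) in bins of 1 Mb along chromosomes 6 and 9 (position in Mb, horizontal axis) for all 8 pooled lists, with controls as thick lines and treatments as dashed lines, Moneyberg in blue and Bolstar in red. On chromosome 6 the 3 Bolstar lists run below the 5 Moneyberg lists over long stretches, and on chromosome 9 all 8 lists cross one another at low shares.

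The named regions follow the same distribution. All 10 of the top gained regions of Moneyberg BABA TW2 were on chromosome 9, as were 8 of 10 for Ina TW2, 8 for MeJA TW3 and 9 for BABA TW3. The largest was gained under BABA TW3, at 31209773 to 31234705 on chromosome 9, with 24.9 kb and 402 sites. It was touched by the lists of all 3 other Moneyberg treatments and of all 3 Bolstar groups, so Moneyberg control was the only list without a base of it. A second BABA TW3 region, at 16732105 to 16752054 on chromosome 9 with 341 sites, was likewise touched by every list except Moneyberg control. The top region of Ina TW2 lay at 49977290 to 49998712 on chromosome 9 (255 sites), that of BABA TW2 at 36971292 to 36987898 (234 sites) and that of MeJA TW3 at 22645692 to 22664832 (210 sites), also on chromosome 9. Every top gained region of the 4 Moneyberg treatments was touched by the list of at least 1 other Moneyberg treatment.

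Of the 10 top lost regions in Moneyberg, those on chromosome 9 numbered 6 for BABA TW2, 8 for Ina TW2, 10 for MeJA TW3 and 8 for BABA TW3. The top lost region in Moneyberg was at 17408476 to 17417904 on chromosome 12 (232 sites), missing under BABA TW3 and touched by the lists of the other 3 treatments. The BABA TW2 list lacked 3 control regions on chromosome 5, at 38308616 to 38320921 (179 sites), 14029864 to 14040816 (171 sites) and 35003205 to 35015856 (167 sites), all touched by the other 3 treatment lists. In Bolstar, 6 of the 10 top gained regions of each treatment were on chromosome 9, as were 8 of the top lost for BABA TW2 and 9 for Ina TW2. The top gained region under BABA TW2 was at 27549775 to 27573779 on chromosome 4 (24.0 kb, 291 sites). Under Ina TW2 it was at 5162323 to 5177864 on chromosome 6 (15.5 kb, 308 sites), a region not touched by Bolstar BABA TW2 but by all 5 Moneyberg lists. A control region at 37067118 to 37088235 on chromosome 9 (235 sites) was lost under both Bolstar treatments.

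The control lists of the cultivars were compared in the same units. Their difference joins genotype with the scale of each list, since lower limits were 65 sites in Moneyberg control and 78 in Bolstar control. With 1 list each and unknown depth, it is not a measure of genotype alone. Bolstar control and Moneyberg control had a Jaccard index of 0.863, lower than any comparison of treatment with control, and the 15 pairs of a Moneyberg and a Bolstar list ranged from 0.857 to 0.878. Bolstar control had 1151 regions with no base in Moneyberg control, and lacked 3332 of the Moneyberg control regions, 1910 of which were below the smallest Bolstar control region. The numbers at the common minimum of 85 sites were 985 and 887. Bases listed in all 5 Moneyberg groups and in no Bolstar group amounted to 9.19 Mb, and the converse to 8.62 Mb.

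**Figure D4:**
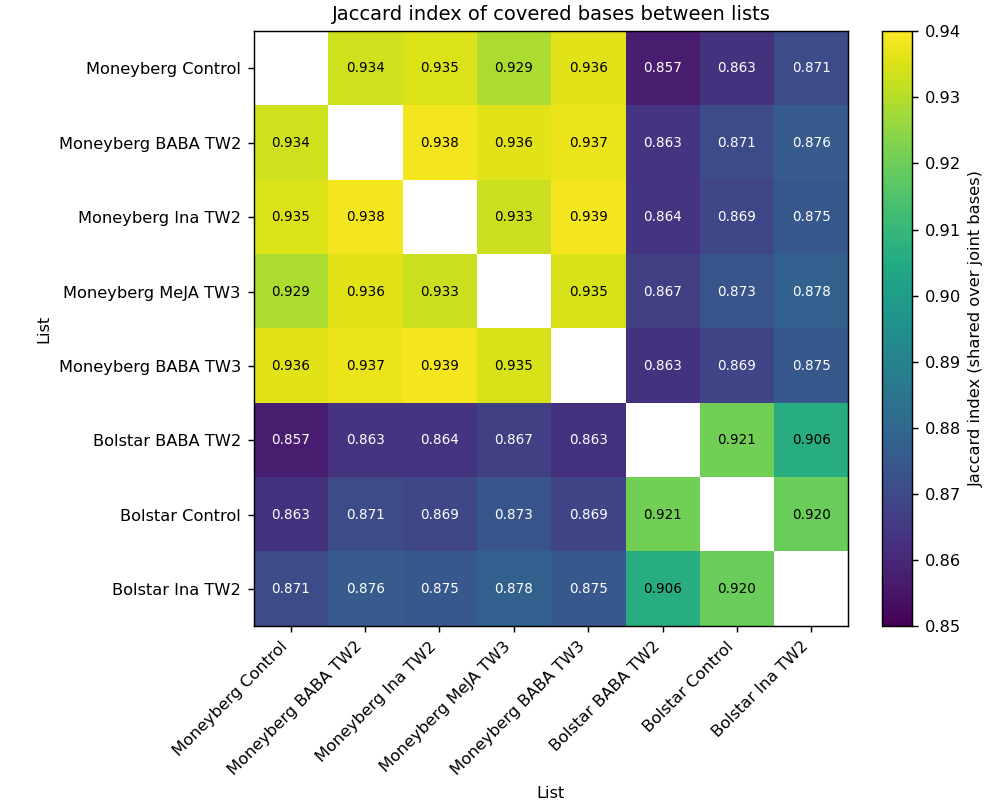
Jaccard index of covered bases (colour and printed value) for every pair of the 8 pooled lists, with lists on both axes. Pairs within Moneyberg lie at 0.929 to 0.939, pairs within Bolstar at 0.906 to 0.921, and pairs between cultivars at 0.857 to 0.878.

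Jaccard indices on chromosome 6 were 0.836 to 0.862 within Bolstar, 0.956 to 0.966 within Moneyberg and 0.767 to 0.811 between cultivars. Only chromosome 9 had lower indices between cultivars, at 0.461 to 0.526, and there pairs within a cultivar were low too. Counted by bins that separate the cultivars, chromosome 6 came first. In 38 of the 50 bins of 1 Mb on chromosome 6 all 3 Bolstar lists had a smaller listed share than all 5 Moneyberg lists, and in 22 the mean difference was at least 5 percentage points. From 20 to 34 Mb the mean share was 70.6% in Moneyberg and 61.3% in Bolstar, and from 11 to 12 Mb it was 45.4% and 17.4%. Of the 10 top regions that Bolstar control lacked, 7 were on chromosome 6, led by 12346823 to 12384777 (38.0 kb, 637 sites) and 5211858 to 5252152 (40.3 kb, 531 sites). Both were touched by all 5 Moneyberg lists, but also by Bolstar Ina TW2, and not by Bolstar BABA TW2. Of the 69 bins of chromosome 12, all Bolstar lists were higher than all Moneyberg lists in 29 and lower in 5, with 82.1% against 70.7% from 38 to 39 Mb. The top region present in Bolstar control and not in Moneyberg control was at 17371095 to 17386128 on chromosome 12 (761 sites), and 42839245 to 42864721 on that chromosome (487 sites) came next. Both were touched by the other Bolstar lists, but also by 3 and by 1 of the 5 Moneyberg lists. On chromosome 9 Bolstar was higher by at least 5 percentage points in 9 bins, with 36.5% against 24.2% from 39 to 40 Mb, and lower by as much in 4, with 17.6% against 40.2% from 5 to 6 Mb.

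BABA and Ina in time window 2 were given to both cultivars, which allowed a comparison of the same elicitor in different genotypes. For BABA TW2, 72 of the 906 regions gained in Moneyberg touched a region gained in Bolstar (7.9%), where draws averaged 52.5, and 123 of the 1516 lost regions did (8.1%), where draws averaged 44.9. For Ina TW2 the numbers were 113 of 834 gained regions (13.5%) against a mean of 138.7, and 99 of 1441 lost regions (6.9%) against 19.3. The other 6 pairs of a Moneyberg and a Bolstar treatment shared 7.1% to 15.9% of gained and 5.0% to 11.2% of lost regions. These shares depended on the Bolstar list. With Bolstar BABA TW2 the other Moneyberg treatments shared 7.1% to 7.8% of gained and 9.2% to 11.2% of lost regions. With Bolstar Ina TW2 they shared 14.8% to 15.9% and 5.0% to 6.6%. Beside these, BABA TW2 was higher for gained and lower for lost regions, and Ina TW2 the reverse. These differences carry no spread. Over all 8 pairs of a Moneyberg and a Bolstar treatment, observed counts were 0.81 to 1.37 times the draws for gained regions and 2.74 to 5.13 times for lost regions. Lost regions were small (medians of 70 to 72 sites in Moneyberg, against 154 in its control), so these ratios can exceed 1 by size alone. They were 1.62 to 2.94 when each list was first cut to regions at or above its median site number. A region lost in that setting may still touch a smaller region of the other list. For Moneyberg BABA TW2, 1062 regions were lost in this way, against 6 with no base in the whole treatment list. The ratios of that setting therefore do not show sharing of large absent regions. Gained draws can hit the compared list's own regions, so gained ratios near 1 do not show an absence of sharing. BABA TW2 ranked 1 of 8 for gained and 8 of 8 for lost regions, and Ina TW2 ranked 8 of 8 and 1 of 8. The ratios followed the Bolstar list. Pairs with Bolstar BABA TW2 gave 1.25 to 1.37 for gained and 2.74 to 3.37 for lost regions. Pairs with Bolstar Ina TW2 gave 0.81 to 0.95 and 4.29 to 5.13. The ranks thus cannot separate a match of elicitor from the choice of Bolstar list. Reciprocal overlap of 50% also changed which regions counted as gained, 3353 for Moneyberg BABA TW2 in place of 906, and as lost. The ratios for gained regions were then 0.76 for BABA TW2, below the draws, and 0.67 for Ina TW2. Those for lost regions were 1.97 and 2.11. They describe other sets of regions, most of the gained ones with bases in the control list.

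Within Moneyberg, BABA was given in time windows 2 and 3, which allowed the same elicitor at different times to be set beside different elicitors. Of the regions gained in BABA TW2, 40.5% touched a region gained in BABA TW3, and of the lost regions 63.1%. The 6 pairs of treatments ranged from 39.5% to 41.7% for gained and from 51.4% to 73.0% for lost regions, so the BABA pair lay within the range of the other pairs. Bases gained in both BABA treatments amounted to 7.58 Mb, against 7.18 Mb when lists were exchanged at random and 7.36 Mb for independent sets. Bases lost in both amounted to 8.24 Mb, against 7.96 Mb and 0.49 Mb. The exchanged lists keep the shared control and the number of lists that hold each segment. Nearly all of the excess of lost bases over independent sets thus arises without setting the control apart. It cannot be assigned to the shared control alone. Between cultivars, whose controls differ, lost bases were 5.84 to 7.75 times the overlap of independent sets. Part of the remaining excess may also come from the shared control. Bases lost in both at the common minimum of 85 sites were 5.62 Mb against 8.26 Mb for exchanged lists, a turn to a deficit, and bases gained in both were 9.05 Mb against 7.15 Mb.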

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

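The tests of sites per kb and of changes particular to each elicitor on chromosome 9, of sites and of depth on chromosome 6, of the scaling of region sizes, of the direction of region numbers and of Moneyberg material were chosen after the results were seen.

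With the same elicitor, some measures moved away from the control in opposite directions in the cultivars and others in the same direction, and none of these differences was tested, since each rests on 1 list per group. The BABA TW2 list minus its control was 1.25 Mb of covered sequence in Moneyberg and -3.5 Mb in Bolstar, while its number of regions fell in both (-1726 and -2599). The Ina TW2 list minus its control was -1598 regions in Moneyberg and 3321 in Bolstar, while its covered sequence rose in both (0.24 Mb and 1.51 Mb). The covered difference for BABA TW2 at the common minimum of 85 sites was 7.56 Mb and 1.98 Mb, so the opposite directions ended, and the numbers of regions still fell in both (-308 and -1581). For Ina TW2 the number of regions still differed in sign there (-461 and 1169), and the covered difference came to do so (5.35 Mb and -9.53 Mb).

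The numbers of regions differed 1.36-fold between lists and covered sequence 1.011-fold. A filter on sites per region as the only difference is argued against: at the common minimum the median number of sites still differed 1.098-fold between lists. The median stood at a nearly fixed multiple of each list's own lowest number, with the highest multiple 1.017 times the lowest, where a filter alone on Moneyberg control gives 1.094, so a scale set separately for each list during calling may account for the numbers. Moneyberg material in the Bolstar Ina libraries, in an amount that would add sites, is argued against by chromosome 6, where its regions between the ends held 18.22 sites per kb, as in the other Bolstar lists (18.22 and 18.23) and below the Moneyberg lists (19.06 to 19.08). An effect of elicitors on the number of regions remains open, since 5 of 6 treatment lists held fewer regions than their control and no replicate error exists.

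The treatment and control lists differed most on chromosome 9. Region calls that differ between any pair of lists may account for this: the 6 pairs of Moneyberg treatments had a mean Jaccard index of 0.565 there, as low as that of control with treatment. A change common to the elicitors as the source on this chromosome is argued against, since control and treatments had a mean index of 0.568, above the lowest pair of treatments at 0.559. Changes particular to each elicitor stay open: the BABA pair ranked 3 of 6, and the Bolstar treatments had an index of 0.515 with each other, below the 0.535 and 0.558 of BABA TW2 and Ina TW2 with the control. Regions between the ends of chromosome 9 held at most 15.9 sites per kb in any list, below the 16.3 of the lowest other chromosome, so fewer usable sites there may contribute, and a sequence difference of both cultivars from the reference remains open, as untested.

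The Bolstar lists lay below the Moneyberg lists along chromosome 6. Chance as the reason that lists group by cultivar is argued against by the 56 splits of the 8 lists into 5 and 3. Over all chromosomes the real split separated 291 of 812 bins, and the highest other split separated 65. On chromosome 6 the real split separated 38 bins and the highest other split 8. The smallest share that such splits can reach is 1 in 56. Lower limits also differed by cultivar, at 65 to 71 sites in Moneyberg and 71 to 85 in Bolstar. On the stretch from 20 to 34 Mb 91.4% of 70 identical intervals held fewer sites in Bolstar control and none held more, with 11735 sites in all against 12102 in Moneyberg control. Off that stretch 5.3% held fewer and 9.2% more, but depth remains open, since the score counts sites and not reads and intervals called identically are those where depth did not change the call. A stretch of chromosome 6 whose sequence differs between the cultivars, with Bolstar the further from the reference, is a candidate explanation, and a difference in methylation between the genotypes remains open, as untested.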

How the results depend on the processing

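The common minimum of 85 sites and the omission of chromosome 9 were chosen after seeing the data. Values follow the order BABA TW2, Ina TW2, MeJA TW3 and BABA TW3 in Moneyberg, BABA TW2 and Ina TW2 in Bolstar, each against its control, then Bolstar control against Moneyberg control. No paired analysis was possible because each group has 1 pooled list. For the same reason read coverage minimums, logit offsets, low-level filters and omitted replicates were not run, nor were gene-based alternatives, which need an annotation of the build. The lists hold no depth, so its limits cannot be given. Causes were not tested except where stated.

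Jaccard indices for regions at or above their list's median site number were 0.880, 0.881, 0.874, 0.881, 0.861, 0.855 and 0.765. At the common minimum they were 0.931, 0.930, 0.929, 0.932, 0.926, 0.926 and 0.860, and without chromosome 9 0.951, 0.953, 0.947, 0.954, 0.941, 0.939 and 0.883. Merging regions within 100 bases left the 6 treatment values as they were to 3 decimals and gave 0.864 between controls. Under each of these settings the control pair stayed below all treatment comparisons.

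The share of regions touching the control was 89.2%, 89.3%, 89.8%, 89.5%, 87.1%, 78.3% and 77.2% with reciprocal overlap of 50%. It was 95.8%, 95.8%, 95.8%, 95.9%, 95.8%, 90.3% and 94.1% for regions at or above the median, and 96.4%, 96.6%, 96.2%, 96.7%, 96.3%, 95.7% and 92.6% in bases. Merging kept all 7 shares within their intervals.

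A distance of 1000 bases kept every gained and lost count within 1.5 times. Regions at or above the median compared with the whole other list gave 14, 14, 12, 12, 8, 19 and 19 gained and 6, 16, 8, 12, 11, 11 and 79 lost, since absent regions are mostly small. Gained minus lost then reversed to 8 for BABA TW2 and 4 for MeJA TW3 in Moneyberg. At the common minimum gained regions numbered 505, 446, 537 and 431 in Moneyberg and 556 for Bolstar Ina TW2, and lost regions 302, 386, 347 and 365 in Moneyberg, 1110 for Bolstar BABA TW2 and 887 between controls. Gained minus lost reversed to 203, 60, 190 and 66 in Moneyberg, -123 for Bolstar Ina TW2 and 98 between controls, and by construction this setting removes regions below other lists' limits. Without chromosome 9 gained regions were 470, 457, 450 and 452 in Moneyberg, 372 for Bolstar BABA TW2 and 716 between controls, and lost regions 939 for Moneyberg Ina TW2 and 413 for Bolstar Ina TW2.

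For the same elicitor in both cultivars, observed over drawn counts of BABA gained, Ina gained, BABA lost and Ina lost regions were 0.76, 0.67, 1.97 and 2.11 with reciprocal overlap. They were 1.17, 0.76, 1.89 and 2.94 for lists cut to regions at or above the median, and 1.09, 0.73, 2.72 and 4.69 without chromosome 9. Reciprocal overlap and the cut at the median also changed which regions counted as gained or lost, so their ratios describe other sets of regions. For BABA TW2 with BABA TW3, gained and lost ratios under these 3 settings, in the same order, were 1.58 and 3.78, 1.26 and 10.27, and 1.35 and 20.11, against 1.22 and 13.66 as deposited. The draws treat these sets as independent although they share a control and lost regions are mostly small. Lost ratios above 1 thus arise without a common change (in lost bases, exchanged lists gave 7.96 of the observed 8.24 Mb).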

Other observations

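The tests of both hypotheses in this part were set before their results were seen, and the spread over chromosomes and the comparison of Bolstar Ina TW2 with the Moneyberg lists were added afterwards. Within each cultivar, every list held some sequence that no other list of the cultivar held. In Moneyberg this was 4.81 Mb for the control, 4.40 Mb for MeJA TW3, 3.95 Mb for BABA TW2, 3.46 Mb for Ina TW2 and 3.40 Mb for BABA TW3. Sequence missing from 1 list alone was 4.19 Mb for MeJA TW3 and 3.72 Mb for the control. The order depended on the lower limits. At the common minimum of 85 sites the control alone held 2.66 Mb, the least of the 5 lists, and MeJA TW3 alone held 5.57 Mb. Sequence missing from MeJA TW3 alone was then 2.14 Mb, and from the control alone 4.61 Mb, the most of the 5 lists. In Bolstar, with 3 lists, Ina TW2 alone held 12.1 Mb, BABA TW2 9.24 Mb and the control 7.68 Mb. This order turned at the common minimum, with 5.43 Mb for Ina TW2, 11.45 Mb for BABA TW2 and 8.69 Mb for the control. The Bolstar Ina TW2 list shared 5.77 Mb with all 5 Moneyberg lists that the other 2 Bolstar lists lacked, against 2.99 Mb for BABA TW2 and 2.19 Mb for the control. With the same minimum it shared 1.48 Mb in this way, the lowest of the 3.

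Other runs of bins separated the cultivars beside chromosome 6. Bolstar was higher on chromosome 5 from 29 to 37 Mb (84.1% against 80.7%), on chromosome 10 from 32 to 39 Mb (89.0% against 86.0%) and on chromosome 12 from 20 to 26 Mb (82.9% against 78.2%). It was lower on chromosome 4 from 52 to 59 Mb (22.7% against 25.3%). In the whole set 291 of 812 bins separated the cultivars, or 35.8%, where lists without any grouping would give 3.6%.

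A first hypothesis was that elicitors change the same bases in both cultivars, in which case the control pair should stand apart from the 6 treatment lists more than any other pair of a Moneyberg and a Bolstar list. The control pair ranked 11 of 15, with 0.443 Mb setting it apart, and the pair of Moneyberg control and Bolstar Ina TW2 ranked 1 with 0.730 Mb. A common effect of this kind thus did not outweigh the other differences between lists. The amounts were not scaled for how distinct each list is. Every pair with Bolstar control ranked 9 or lower. The first pair joined the lists with the lowest limits of their cultivars (65 and 71 sites). The rank therefore cannot speak against a smaller common effect. A second hypothesis was that the same elicitor gains the same bases in both cultivars. Among the 8 pairs of treatments, the same-elicitor pairs ranked 4 (Ina TW2, 0.852 times the overlap of independent sets) and 5 (BABA TW2, 0.849 times), below pairs of different elicitors at up to 0.929. All 8 ratios were 0.83 to 0.929. Counting only bases held by at least 1 list lowers these ratios, so values below 1 do not show a shortfall of sharing. The largest of the 10 differences between a different-elicitor and a same-elicitor pair was 0.081, with a standard error of 0.034 from leaving out each chromosome in turn. That is 2.4 standard errors, short of the 3.11 that the largest of 10 would need. This spread is over chromosomes of the same pooled lists, and not over plants or lists. By number of gained regions BABA TW2 ranked 1 of 8 (1.37 times the draws) and Ina TW2 ranked 8. Those ratios followed the Bolstar list, so these ranks cannot decide, and this hypothesis stays open. The ranks set as its test carried no spread. For lost bases Ina TW2 ranked 1 of 8 (7.75 times) and BABA TW2 ranked 8 (5.84 times). There too all pairs with Bolstar Ina TW2 (7.14 to 7.75 times) lay above all pairs with Bolstar BABA TW2 (5.84 to 6.86 times). The overlap of independent sets made no allowance for the small size of lost regions.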
